A study of Thielaviopsis ethacetica with 8 samples.

How the data were processed

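RNA was measured in the fungus *Thielaviopsis ethacetica*, strain JCM 6961, which causes pineapple sett rot of sugarcane. Per the labels' protocols, spores in liquid medium (200 µL per tube) stood in one compartment of a divided Petri dish for 2 days at 28 °C. The other compartment held 100 µL of a bacterial suspension in the exposed group and no bacteria in the control group. The compartments were joined by the air of the dish. Libraries of polyadenylated RNA were made with a stranded kit and sequenced on an Illumina HiSeq 2500, per the labels' protocols. The series held 8 samples, 4 per group.

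Per the submitters' processing notes, bcl2fastq 2.18.0.12, Trimmomatic 0.36, HISAT2 2.0.4, featureCounts and DESeq2 1.6.3 were used by the authors, with no order or options stated. The deposited table of counts held whole reads per transcript, not normalized, for 6863 transcripts, and the smallest total count of a listed transcript over the 8 libraries was 10. The strand setting of the counting and the treatment of reads with several matches are not given in the sources used here, so overlapping genes and near-identical copies are uncertain. The deposited normalized values (a signal scaled per library) equalled the count divided by a median-ratio size factor per library, with a largest relative deviation of 5.4e-10. The authors' deposited table of filtered results gave a log2 fold change, its standard error, a test score, a p-value, an adjusted p-value and a weight for 677 transcripts. Its score equalled the absolute log2 fold change minus 1, divided by the standard error and signed by the direction. Where the weights came from is not stated. The deposited gene models, made with AUGUSTUS per the file's source column, comprised 7007 genes and 7123 transcripts on 71 scaffolds. Coding lengths were multiples of 3 in 99.9% of transcript models, so they hold no untranslated regions and are called coding lengths here. Coordinates are those of the gene models and scaffolds are numbered as in that file. The name of the genome build is not given in the sources used here.

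The columns of the tables were named C1 to C4 and P1 to P4. The C columns were matched to the control samples by letter and number. The letter P occurs in no label, and its columns were assigned to the exposed samples because they were the columns that remained. Total counts ranged from 5459916 to 27882867 per library. In pairwise comparisons within groups, the chi-square statistic per degree of freedom ranged from 14.41 to 213.57, so no pair of libraries agreed within sampling noise. The labels do not say that replicates came from separate plates or cultures, so p-values measure only the spread between these samples. Groups shared replicate numbers, and no label says what a number marks.

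Differential expression was tested on the deposited counts with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, which kept 6625 transcripts, TMM factors, glmQLFit with robust=TRUE and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the transcripts tested. A transcript was called changed at an adjusted p under 0.05, and changed at least 2-fold where the absolute log2 fold change was also at least 1. The common biological coefficient of variation was 0.185. Standard errors (SE) of log2 fold changes were the absolute value divided by the square root of the F statistic. Levels are CPM, counts scaled by the TMM-adjusted library size, given as mean ± SD over 4 libraries, and log2 CPM used a prior count of 2. Gene structure classes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Neighbouring genes were tested by 10000 permutations of the calls over gene positions, one-sided, with 1 transcript per gene model and untested gene models passed over. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

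The transcripts named by identifier were chosen by a rule set before the data were examined. They are the 2 with the largest rise and the 2 with the largest fall among those past the threshold with a mean of at least 10 CPM and no overlap between the groups. The files used here do not pair identifiers with gene names, and 41 gene lists fixed beforehand (heat shock proteins, transporters, oxidoreductases and others) could not be filled, because no functional annotation, genome sequence or protein sequence was used here. None of these 41 lists was tested.

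The tests were also run on simulated data, with settings taken in part from a fit to the real libraries. For the comparison of exposed with control libraries, counts for 6625 genes were drawn from the real control levels, library sizes and dispersions, with 200 genes changed. The edgeR test recovered 87% of 2-fold and 99% of 4-fold changes, 7.5% of its calls were unchanged genes, and a simulation with no change gave 0 calls. The simulated changes were few and held as many rises as falls. The simulation therefore does not test the calls or the scaling where most transcripts change and large changes are mostly falls. With camera, 0% of random classes of the real sizes had an unadjusted p under 0.05 in unchanged data, whose genes were independent. The permutation of neighbours gave p under 0.05 in 5.0% of 200 simulated sets of calls without clustering. These calls were drawn independently for each gene, so a share near this follows from the design. It checks the working of the test only and not its behaviour where genes are correlated.

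The alternatives were RLE factors, library size only, upper-quartile factors, no filter, a filter of at least 50 counts in 4 libraries, robust=FALSE, limma-voom, limma on log2(normalized value + 1), DESeq2 1.42.0, the replicate number as a block, and each library left out in turn. A test against a 2-fold change (glmTreat, and DESeq2 with a threshold of 1 on the log2 scale) and further settings of the neighbour and class tests were added after the data had been seen.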

Results

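The data were 8 libraries of polyadenylated RNA from the sugarcane pathogen *Thielaviopsis ethacetica*, 4 from cultures kept in divided dishes without bacteria (control) and 4 from cultures that shared the air of the dish with bacteria (exposed). Total counts were 27882867, 12909241, 13573929 and 9032083 in control replicates 1 to 4, and 5459916, 13006131, 18233975 and 8799296 in exposed replicates 1 to 4. The exposed libraries listed 96, 44, 31 and 72 transcripts at 0 counts, and the control libraries 0, 12, 14 and 9. The single comparison of the design asks how the transcriptome of the fungus differed where it shared air with the bacteria.

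The groups were far apart across the transcriptome. Spearman correlations of log2 CPM across genes were 0.975 to 0.994 within the control group, 0.971 to 0.993 within the exposed group and 0.801 to 0.887 between groups. The mean within groups exceeded the mean between groups by 0.13 (exact permutation test over 35 splits, one-sided p = 0.0286, the smallest that 35 splits allow). The first principal component held 85.3% of the variance and placed control libraries between -55 and -44.1 and exposed libraries between 41.8 and 58. On the second component (6.05%) exposed replicates 1 to 4 lay at -18.7, -14.9, 20.5 and 12.6, and control replicates 1 to 4 at 9.5, 6.1, -3.3 and -11.7.

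**Figure D1:**
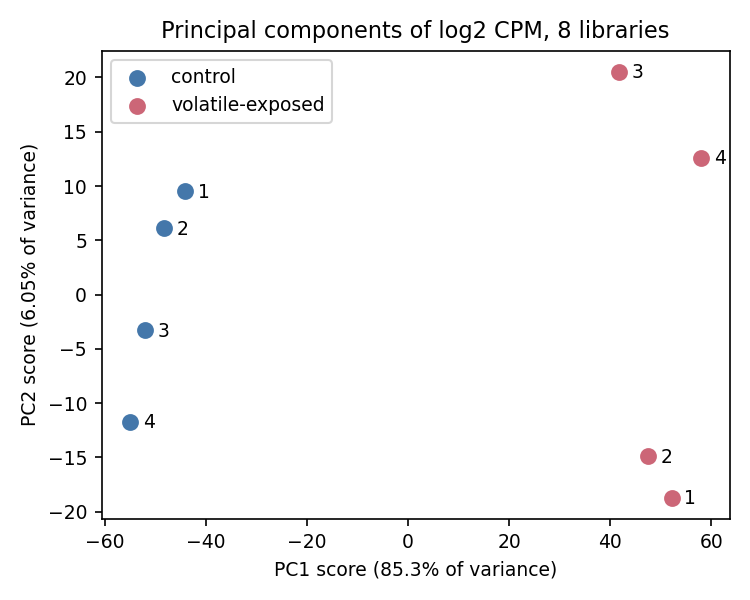
Scores of the 8 libraries on the first and second principal components of log2 CPM over tested transcripts, with the replicate number beside each point. Control libraries lie between -55 and -44.1 on the first component and exposed libraries between 41.8 and 58.

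Most tested transcripts differed between exposed and control libraries, by any size of change, and large changes were mostly falls. Of 6625 transcripts tested, 4077 changed (61.5%), of which 2101 rose and 1976 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold change was found for 1518 transcripts, of which 495 rose and 1023 fell, so that falls made up 67.4%. At least 4-fold, 89 rose and 417 fell. At least 16-fold, 16 rose and 106 fell, and at least 64-fold, 6 rose and 30 fell. A mean of at least 10 CPM in control and under 0.5 CPM in exposed libraries was seen for 11 transcripts, and the reverse for 4. All exposed libraries lay above all control libraries for 1899 transcripts and below them for 1826, where chance gives 2.86% of transcripts in both directions together. The even balance of all calls depended on the scaling: rises were 51.5% of the changed transcripts with TMM factors, 57.7% with library size only, where the median log2 fold change of all transcripts was 0.12 and not 0.031, and 45.0% with upper-quartile factors.

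**Figure D2:**
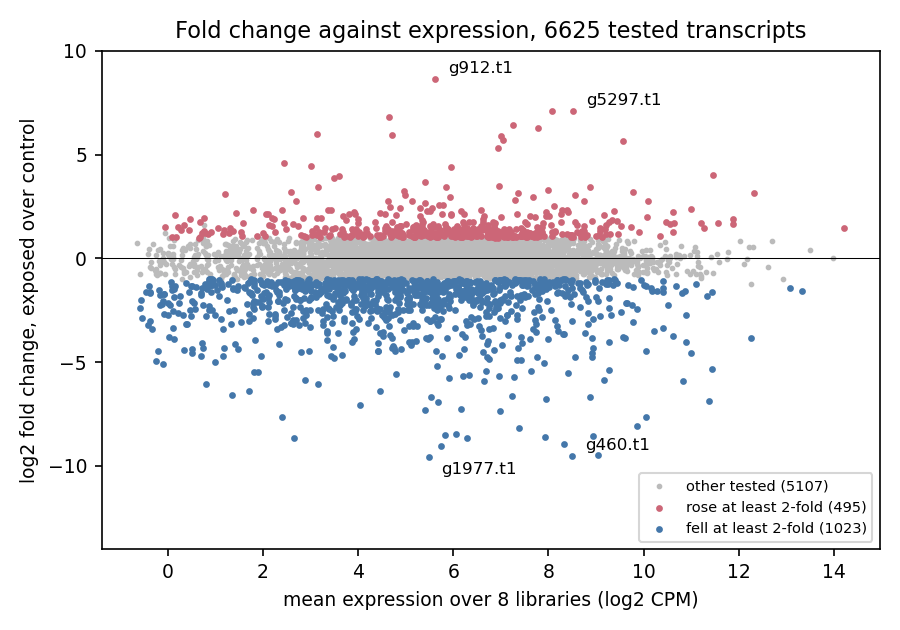
Log2 fold change of exposed over control libraries against mean expression over the 8 libraries (log2 CPM), one point per tested transcript, with the 4 named transcripts marked. Colour marks the 495 transcripts that rose and the 1023 that fell at least 2-fold, and falls reach further from 0 than rises.

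Among the transcripts named by identifier, g912.t1 had the largest rise. It lies on scaffold 19 at 425771–427664 on the plus strand and has 8 coding exons and a coding length of 1338 nt. Its level went from 0.218 ± 0.145 CPM in control to 98.6 ± 40.0 CPM in exposed libraries (SD, n = 4 per group), a log2 fold change of 8.62 (SE 0.437, edgeR adjusted p = 1.97e-07). The control level rests on 15 reads over the 4 libraries. The second, g5297.t1, lies on scaffold 6 at 653161–654286 on the minus strand, with 3 coding exons and a coding length of 774 nt. It went from 5.52 ± 2.53 to 729.8 ± 659 CPM (SD, n = 4 per group), a log2 fold change of 7.10 (SE 0.681, edgeR adjusted p = 1.67e-05). Exposed replicate 3 stood at 1710 CPM and the other exposed libraries at 342 to 523 CPM, and without that library the log2 fold change was 6.24.

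The largest fall was that of g1977.t1, on scaffold 29 at 48021–49277 on the plus strand, with 3 coding exons and a coding length of 954 nt. It stood at 89.5 ± 13.2 CPM in control and 0.0956 ± 0.0938 CPM in exposed libraries (SD, n = 4 per group), a log2 fold change of -9.58 (SE 0.289, edgeR adjusted p = 1.30e-08). The exposed libraries held 0, 3, 1 and 1 reads of it, 5 in all, with an exact 95% Poisson interval of 1.62 to 11.7 reads that covers counting error only. Without exposed replicate 2 the log2 fold change was -10.32. The transcript g460.t1, on scaffold 16 at 484722–485899 on the minus strand, has 3 coding exons and a coding length of 711 nt. It was abundant in control libraries at 726.4 ± 111 CPM and stood at 0.906 ± 0.480 CPM in exposed libraries (SD, n = 4 per group), a log2 fold change of -9.52 (SE 0.318, edgeR adjusted p = 1.91e-08). The order of g1977.t1 and g460.t1 held in most alternatives but was reversed in some, as with limma-voom (-9.4 and -9.63). The nearest tested genes on either side had log2 fold changes of -1.72 and -2.98 for g1977.t1, -0.405 and -2.15 for g460.t1, 0.062 and 0.643 for g912.t1, and -0.311 and 0.883 for g5297.t1. Of these neighbours, those at -0.405, 0.062 and -0.311 did not pass the test (edgeR adjusted p = 0.0712, 0.619 and 0.117).

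**Figure D3:**
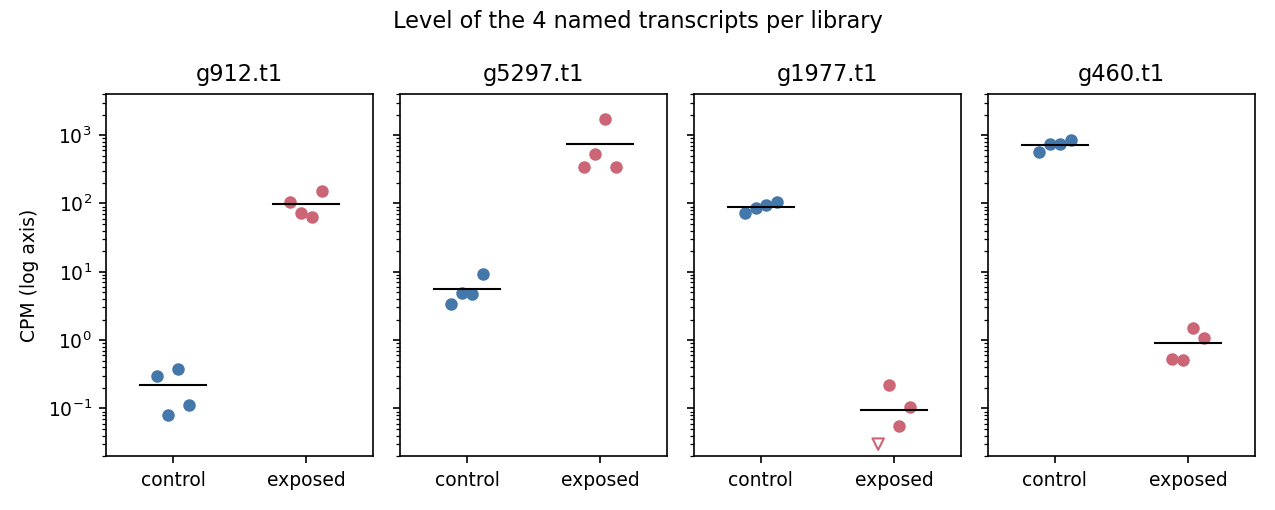
CPM of the 4 named transcripts in each library on a log axis, with control libraries in blue, exposed libraries in red, and the group mean as a horizontal line. The open triangle marks a library with 0 reads of g1977.t1, drawn at the foot of the axis.

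The changes reached the most abundant transcripts. Transcripts that fell at least 2-fold held 25.1% ± 1.9 of the TMM-adjusted library size in control and 6.06% ± 1.4 in exposed libraries. Those that rose at least 2-fold held 5.42% ± 0.30 and 17.1% ± 2.5 (SD, n = 4 per group). TMM factors were 0.962 to 0.976 in control and 0.975 to 1.076 in exposed libraries, so these are not exact shares of reads. These shares describe transcripts chosen for their change. The transcript with the highest mean over the 8 libraries, on scaffold 11 at 294341–296005 on the plus strand, has 2 coding exons and a coding length of 1596 nt. It rose from 10260 ± 1217 to 27890 ± 8196 CPM (SD, n = 4 per group), a log2 fold change of 1.44 (SE 0.226, edgeR adjusted p = 0.000366). Of the 20 transcripts most abundant in control libraries, 3 rose, 10 fell and 7 did not pass the test. Of the 20 most abundant in exposed libraries, 10 rose, 3 fell and 7 did not pass, and 12 transcripts were in both sets. Among the 100 most abundant of each group, 54 of the control set fell and 10 rose, 34 of the exposed set rose and 18 fell, and 62 transcripts were shared. Because each set was chosen by its level in one group, its balance leans towards that group.

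Falls were most frequent among weakly expressed transcripts. With transcripts ordered by mean expression and divided into 10 groups of like size, 232 of the 663 transcripts in the lowest group fell at least 2-fold and 52 rose. In groups 4 to 9 the share that fell at least 2-fold was 8.91% to 11.9%. In the highest group 17.3% fell and 9.95% rose at least 2-fold.

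At the preset correlation, genes with short coding sequences were lower in exposed libraries relative to other genes, and genes with long coding sequences were higher, but neither call was robust. Log2 CPM, which is not scaled by length, rose more steeply with coding length in every exposed library than in any control library. Over genes longer than 450 nt its slope on log2 coding length was 0.132 to 0.268 in control and 0.319 to 0.399 in exposed libraries. As many classes passed the threshold in 14 of the 35 splits of the libraries, the real one included. Of 452 transcripts with a coding length under 450 nt, 76 rose, 169 fell and 207 did not pass, with a median log2 fold change of -0.208 against 0.039 for other transcripts (camera, adjusted p = 0.0248; adjusted p = 0.6 with an estimated correlation). Of 700 transcripts with a coding length over 3000 nt, 275 rose, 149 fell and 276 did not pass, with a median of 0.191 against -0.005 (camera, adjusted p = 0.0416; adjusted p = 0.6 with an estimated correlation). The call for short coding sequences was also lost without control replicate 4 (adjusted p = 0.0853). That for long coding sequences was lost without control replicate 2, 3 or 4 or exposed replicate 4 (adjusted p = 0.0513, 0.0539, 0.0941 and 0.0886). At least a 2-fold fall was found for 20.6% of the short class and 9.29% of the long class. The count of changed transcripts adjusted over the list alone was 235 in the short class and 423 in the long class.

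Exon number gave no class that passed the camera test. Of 1284 single-exon genes, 432 rose, 361 fell and 491 did not pass (camera, adjusted p = 0.673). Their median log2 fold change was 0.057 and their mean -0.154, against a mean of -0.181 for other transcripts. Camera placed them above other genes, while fry gave a fall on balance (adjusted p = 0.0341). The fry test asks for a shift from 0 and not from other genes, so this fall is not particular to the class. Of 686 transcripts with 5 or more coding exons, 165 rose, 227 fell and 294 did not pass (camera, adjusted p = 0.208). For them fry gave a fall on balance (adjusted p = 0.00763), with a mean log2 fold change of -0.249 against -0.167 for other transcripts. It also gave a fall for the short class (adjusted p = 0.00763) and a rise for the long class (adjusted p = 0.0318). Adjusted over the list alone, 793 single-exon genes and 385 genes with 5 or more exons changed.

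Tested genes that changed lay next to each other more often than random placement gives. Neighbours are tested genes with no other tested gene between them, and untested gene models were passed over. Both genes changed in the same direction in 1423 of 6553 adjacent pairs, against 1242 expected (ratio 1.15, one-sided permutation test, p = 0.0001, the smallest that 10000 permutations can give). For changes of at least 2-fold there were 299 pairs against 192.9 expected (ratio 1.55, permutation p = 0.0001). Of these, 236 pairs fell together against 156.3 expected, and 63 rose together against 36.5 expected. Runs of at least 3 consecutive tested genes changed by any size in one direction numbered 314 against 263.3 expected (ratio 1.19, permutation p = 0.0001). Those changed at least 2-fold numbered 55 against 22.8 expected (permutation p = 0.0001), 43 of falls and 12 of rises. An untested gene model lay inside 7 of the 55 runs. An alternative with only pairs that have no untested gene model between was added after the data had been seen. It gave 51 runs changed at least 2-fold against 20.9 expected (permutation p = 0.0001). It gave 279 pairs changed at least 2-fold against 184.0 expected (ratio 1.52, permutation p = 0.0001).

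The longest runs of genes changed at least 2-fold held 5 tested genes, and all 5 of these runs fell. Those on scaffolds 18 and 29 each passed over 1 untested gene model. They are described because of their length, after their values had been seen. The run on scaffold 12 at 130532–143834 had a median log2 fold change of -2.25, and its mean log2 CPM was 6.17 ± 0.02 in control and 3.89 ± 0.38 in exposed libraries (SD, n = 4 per group). On scaffold 16 at 550385–558273 the median was -2.18, with 7.30 ± 0.23 in control and 4.42 ± 0.37 in exposed libraries. On scaffold 18 at 347925–360788 the median was -2.69, with 5.14 ± 0.07 and 2.43 ± 0.22. On scaffold 24 at 85369–105527 the median was -1.91, with 6.98 ± 0.07 and 4.70 ± 0.08. On scaffold 29 at 186347–199839 the median was -2.43, with 2.31 ± 0.08 and 0.11 ± 0.45. Runs of 4 tested genes changed at least 2-fold numbered 11 of falls and 3 of rises. The rising runs lay on scaffold 5 at 80725–87599 (median log2 fold change 1.20), scaffold 13 at 138123–146591 (1.56) and scaffold 25 at 16876–27668 (1.67).

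**Figure D4:**
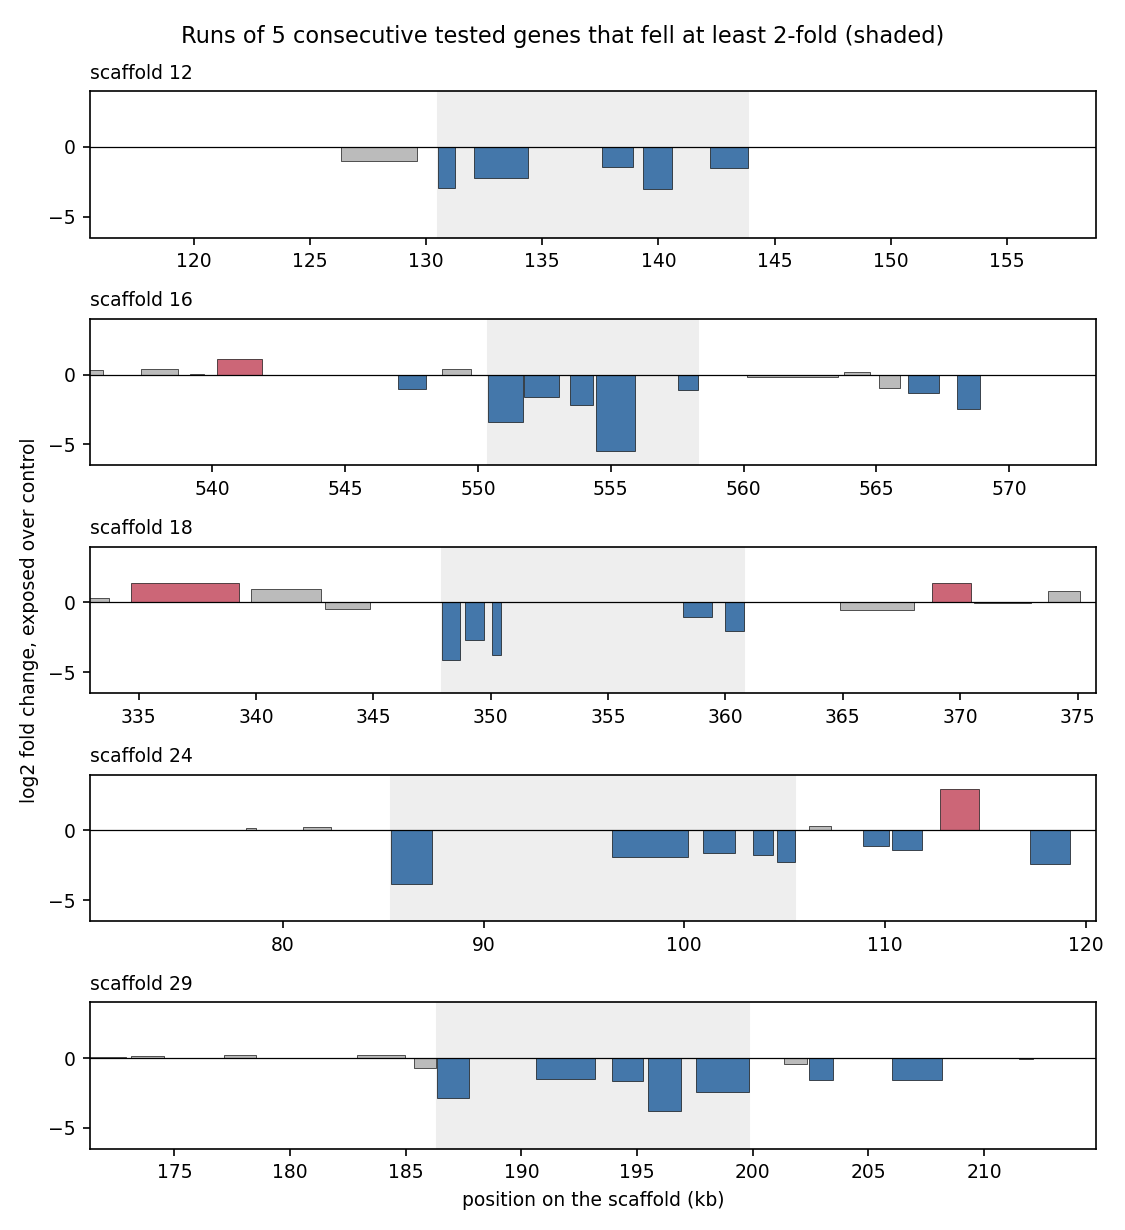
Log2 fold change of each tested transcript (bars, placed and scaled by its position in kb) around the 5 runs of 5 consecutive tested genes that fell at least 2-fold, which are shaded. Blue bars fell and red bars rose at least 2-fold, grey bars did not pass both limits, and the median log2 fold changes of the runs are -2.25, -2.18, -2.69, -1.91 and -2.43 from top to bottom.

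The authors' deposited table listed 677 transcripts, of which 138 rose and 539 fell (79.6%). The smallest absolute log2 fold change in the authors' deposited table was 1.31 and the largest adjusted p was 0.0464. Of the listed transcripts, 670 were tested here, and all 670 changed in the same direction. The other 7 were removed by the filter on low counts. Over the shared transcripts Pearson's r of the log2 fold changes was 0.9999 across genes, which are not independent replicates. Both sets of fold changes come from the same 8 libraries, and the list holds only large changes. The same direction and a high r were therefore nearly fixed in advance, and they show only that the processing was alike. In the authors' deposited table the log2 fold changes of g912.t1, g5297.t1, g1977.t1 and g460.t1 were 8.68, 7.04, -9.72 and -9.55. A test against a 2-fold change, chosen after the data had been seen, called 823 transcripts in edgeR, of which 196 rose and 627 fell, and 692 in DESeq2, of which 676 are in the authors' deposited table.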

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

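The tests of scaling and of weak expression were chosen after the result they bear on had been seen. Of 24 groups of 4 libraries examined, 2 held a library far from the others, and chance gives about 1 in 20. The level of g5297.t1 in exposed replicate 3 was 1710 CPM, while the other exposed libraries lay between 342 and 523 CPM. The gap was 0.868 of the whole range. The mean log2 CPM of the run of 5 tested genes on scaffold 29 was 2.43 in control replicate 4 and 2.27 to 2.28 in the other control libraries, a gap of 0.936 of a narrow range.

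The first pattern is that falls outnumbered rises among changes of at least 2-fold (1023 against 495). Falls made up 59.6% to 73.1% of calls over 5 scalings or tools and after centring on the median gene, so the choice among these did not remove the pattern. Each of them takes totals or most genes as equal between libraries. The median log2 fold change with TMM factors was already 0.031, so centring could alter little. A shift of all transcripts together could not be seen by these, and scaling as a cause stays open to that extent. With TMM factors, weakly expressed genes alone did not account for the pattern in these libraries. The check on genes above the median was not repeated with the other scalings, over which the share of falls moved from 59.6% to 73.1%. Among genes above the median expression 372 of 643 calls were falls (57.9%, Wilson 95% interval 54.0 to 61.6), though their share was lower than the 67.4% of all. The interval treats genes as independent, which neighbours that changed together are not, and it does not measure the spread between cultures. With the 20 most abundant genes left out it was 67.8%. A response of the fungus to the volatiles is a candidate explanation, as a hypothesis found and tested on the same data. Effects of growth stage or culture density were not tested. The design cannot tell volatiles apart from other effects of air shared with bacteria.

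The second pattern is that adjacent tested genes changed together. Reads that run over from one gene model into the next would give little excess among pairs on different strands with coding ends at least 1 kb apart. These had 82 pairs against 49.45 expected (ratio 1.66, permutation p = 0.0001, the smallest possible). Pairs on the same strand were outside this test, so such reads stay open for them. Permuting calls only within 10 groups of like mean expression left 299 pairs against 195.2 expected (ratio 1.53, permutation p = 0.0001). No biological explanation of the excess was tested. Near-identical copies that share reads stay open for pairs on either strand and at any distance, since no sequence was used here.

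The third pattern is the lower level of short coding sequences in exposed libraries, beside the higher level of long ones. Low expression of short genes was argued against, since the difference of -0.253 from other genes (in edgeR's log2 fold changes; -0.247 in the log2 CPM that camera used) lay below the central 95% of 10000 sets matched on expression (-0.132 to 0.030). A length bias between libraries stays open for both the short and the long class. Over genes longer than 450 nt the slope of log2 CPM on log2 coding length was 0.195 ± 0.057 in control and 0.347 ± 0.036 in exposed libraries (SD, n = 4 per group). The difference was 0.152 (exact permutation test, two-sided p = 0.0286). The pattern is therefore not called biological. RNA quality and insert size were not examined.

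For the gene counts, 1 of 35 splits of the 8 libraries, the real one, gave 4077 changed genes and 1518 changed at least 2-fold. The highest other split gave 0 for both. Every other split mixes control and exposed libraries, so the large difference between the groups enters its spread and leaves few calls possible. The splits show that the groups differ, and they cannot exclude a chance difference between the cultures or dishes of the groups. For pairs of neighbours 1 of 35 splits gave 1423 and the highest other 0, which follows from the 0 genes called in the other splits, so the splits say nothing about neighbours. For the structure classes chance was not excluded, since 14 of 35 splits gave at least 2 classes past the threshold, as the real one did, and the highest other gave 3.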

How the results depend on the processing

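The count of changed transcripts stayed within 1.5 times of 4077 under all 18 alternatives (3414 to 4225), and 3522 to 4084 when a library was left out. The count with at least a 2-fold change was 1441 to 1619 when a library was left out, and it moved with the test of size alone: 823 by glmTreat against a 2-fold change, which was chosen after the data had been seen and has a stricter null. The 4 named transcripts kept their direction and call under all 18 alternatives each. The excess of neighbouring pairs kept its call under 15 alternatives (ratio 1.14 to 1.55), and that of 2-fold pairs under 13 (ratio 1.49 to 1.73). The excess of runs of genes changed by any size kept its call under 12 (ratio 1.20 to 2.42), among them the limit of at least 2-fold. Runs changed at least 2-fold were otherwise retested only with no untested gene model between, and not under the replicate block or without a library. Same-numbered libraries of the groups showed no shared deviation: their deviations from the group means correlated at -0.23, -0.35, -0.08 and -0.39 across genes. Differently numbered libraries were not set beside these, so whether the numbers mark a shared order or batch stays open. The replicate block gave 3414 changed transcripts, 1516 with at least a 2-fold change. With an estimated correlation the short class kept its difference of -0.247 and the long class 0.196, and both calls were lost (adjusted p = 0.6; 0.644 with the replicate block as well, added after the data had been seen). The cause was the correlation the test assumes. Leaving out a library gave -0.312 to -0.210 for the short class and 0.155 to 0.235 for the long class. All of the authors' listed transcripts (100%) changed in DESeq2, against 99.0% in edgeR, because the filter removed 7. The alternatives set for the 41 gene lists were not run, since no list could be filled. Depth limits weak transcripts most in exposed replicate 1, with 5459916 counts.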

Other observations

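The tests of position on the scaffold and of residual reads, and the ratios by orientation, were chosen after the results had been seen.

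Neighbouring tested genes that changed together differed by orientation. Both genes changed at least 2-fold in the same direction in 104 of 1922 head-to-head pairs (5.41%), whose starts face each other, in 62 of 1918 tail-to-tail pairs (3.23%) and in 133 of 2713 pairs on the same strand (4.90%). The head-to-head share exceeded the tail-to-tail share (Fisher's exact test, two-sided p = 0.00108; a gene can be in a pair on each side, so pairs are not independent). Against permuted calls the ratio was 1.84 for head-to-head pairs and 1.67 for pairs on the same strand (permutation p = 0.0001 for both, the smallest possible), and 1.10 for tail-to-tail pairs (permutation p = 0.231). Median gaps between coding ends were 1652, 421 and 1551 nt for head-to-head, tail-to-tail and same-strand pairs. The difference in gap was not corrected for, and what the genes of a pair share was not tested.

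Genes near scaffold ends did not fall more often in a detectable way. Within 20 kb of a scaffold end, as marked by the outermost gene models, 119 of 724 transcripts fell at least 2-fold (16.4%), against 904 of 5901 further in (15.3%; Fisher's exact test, two-sided p = 0.445).

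Some transcripts that fell furthest kept a few reads in exposed libraries. For 19 transcripts with at least 100 CPM in control and a fall of at least 64-fold, the exposed level was 0.125% to 0.930% of the control level. Carry-over of reads from control libraries, as the sole source, would give about the same share for every transcript, while the upper quartile of the shares was 2.97 times the lower. Carry-over may still make up part of the lowest shares.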
